A study of Oryza sativa with 12 samples.

How the data were processed

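RNA was sequenced from leaves of 12 samples of the indica hybrid rice TU100, 3 samples in each of 4 treatments. Per the labels' protocols the plants were 1 month old, RNA was extracted with TRIzol and treated with DNase I, and samples were used if the 260/280 ratio was above 2.0 and the RNA integrity number above 8.0. Libraries were read as 125 bp paired ends on an Illumina HiSeq instrument. Samples were placed in the groups water, azoxystrobin, VdAL and VdAL plus azoxystrobin by the treatment given in the labels, and replicates were numbered as in the sample titles.

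The authors deposited a table per sample with a raw read count for each gene ID and closing rows for reads not assigned to a gene. The submitters' processing notes name the aligner TopHat2 2.1.0, the read counter HTSeq 0.6.1 and the package edgeR 3.16.3, without their order or settings. The closing rows in the deposited counts are those that HTSeq writes. The counting mode, the strand setting and the annotation release are not given in the sources used here. The genome build named in the submitters' notes is the pig build Sscrofa10.2. The IDs do not bear that out, since 0 of them start with ENSSSC, the prefix of pig genes in Ensembl, while 40745 start with BGIOSGA and 47693 with EPlOING. The build the reads were aligned to is therefore left open, and no coordinates are given.

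Because the strand setting is not stated, reads from overlapping genes on opposite strands may not be told apart, and reads that fit several near-identical genes were kept out of the gene counts in the row for reads not aligned uniquely. That row held 9.01% to 22.4% of the reads recorded per library, the row for reads outside any gene 42.2% to 49.6%, and the row for reads that fit more than 1 gene 0.646% to 0.833%. The rows for low quality and unaligned reads held 0 reads. All of these were left out of library sizes and tests. Reads recorded per library ranged from 16533415 to 28370970 and reads assigned to genes from 6444650 to 10144564. For a share of reads in a library, the 95% Wilson interval covers counting error only.

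The 88438 IDs were looked up in a table of 39387 rice genes of the japonica assembly ASM3414082v1 by gene ID, locus tag, synonym, Ensembl ID and accession, and 0 matched. Genes are therefore given by ID. The gene lists fixed before the data were examined, which covered respiration, detoxification, defence, hormones, photosynthesis, cell division and other tissues, had 0 members that could be measured and were not tested. The rule that would have named the alternative oxidase genes and the genes of largest change had nothing to work on. In its place stood the part of the rule written for unnamed IDs, which takes per comparison at most 2 IDs up and 2 down by smallest p among those with adjusted p under 0.05. Checks of GC content and gene length were void, because no ID had a value for either.

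Counts were analysed with edgeR 4.0.16 in R 4.3.3. IDs were kept by filterByExpr with the groups and a minimum count of 10, which left 21381 IDs, 20081 starting with BGIOSGA and 1300 with EPlOING. Library sizes were scaled by TMM, with factors from 0.926 to 1.05. A group-means model was fitted to all 12 libraries with the quasi-likelihood functions glmQLFit and glmQLFTest, so that the 4 groups share an estimate of the spread with 8 residual degrees of freedom and a prior of 8.9. The common biological coefficient of variation was 0.188. The 7 comparisons were each treatment against water, the combination against each single treatment, VdAL against azoxystrobin, and the interaction, defined as the log2 effect of VdAL with azoxystrobin minus that without. P-values were two-sided and adjusted by Benjamini and Hochberg over the tested IDs of a comparison, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic, and 95% intervals used the t distribution with the total degrees of freedom. Principal components and correlations between libraries used log2 CPM with a prior count of 2.

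The procedure was tested on simulated data before use. Counts were drawn for the 21381 genes from the means, dispersions and library sizes of these libraries, with 200 genes changed. For azoxystrobin against water, 53 of 100 genes changed 2-fold and 87 of 100 changed 4-fold were called, with 7 false calls, or 4.76% of the calls. For the interaction, 22 of 100 at 2-fold and 74 of 100 at 4-fold were called, with 9 false calls. Overlaps between comparisons that share the water libraries were set beside 20 simulations in which no gene was changed. In these all 12 libraries, water included, were drawn anew, each gene independently.

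Pairs of libraries within a group were compared for duplicates by a chi-square test of their counts, and the lowest chi-square per degree of freedom was 4.24, so no pair agreed within sampling noise. The alternatives fixed before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in 3 libraries, which kept 22384 IDs and so was looser than the main filter, a fit on the libraries of the compared groups alone, the replicate number as a block, removal of the 20 most abundant genes, and leaving out each library in turn. Library sizes without scaling factors, limma 3.58.1 voom with quality weights per group, and the share of reads not aligned uniquely as a covariate were added after seeing the data.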

Results

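Messenger RNA levels were measured by RNA sequencing in leaves of 1-month-old plants of TU100, an indica hybrid rice. The 12 libraries fall into 4 treatments of 3 libraries each, which are water, azoxystrobin, VdAL, and VdAL plus azoxystrobin, called the combination from here on. Azoxystrobin is a strobilurin fungicide that blocks complex III of the mitochondrial respiratory chain. VdAL is named in the labels without an expansion. The layout crosses the presence of VdAL with the presence of azoxystrobin, so each agent can be compared with its absence on either background. The growth description mentions 4 areas without saying which plants came from which. A difference between areas would therefore be part of the treatment differences if each treatment had its own area. Nothing in the labels states that the 3 libraries of a treatment came from separate plants or plots, so the p-values measure the spread between these libraries, which may be technical.

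The reads assigned to genes ranged from 6444650 in combination replicate 3 to 10144564 in water replicate 2, with a median of 7407790. Read counts were given for 88438 gene IDs, and 36532 of them had at least 1 read in some library. After the filter on low counts 21381 IDs were tested. The files do not pair the IDs with gene names and 0 of the IDs matched the reference table, so genes are given by ID and no function is stated for any of them. Levels are in CPM, the read count relative to the library size, with library sizes scaled by the trimmed mean of M-values (TMM), as mean ± SD of 3 libraries. Log2 fold changes have their standard error (SE) from edgeR's quasi-likelihood fit over all 12 libraries. A gene is called changed where its Benjamini-Hochberg adjusted p in that test was under 0.05.

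Libraries of the same treatment correlated at 0.947 to 0.977 (Pearson, log2 CPM of the tested genes), and libraries of different treatments at 0.936 to 0.978. The ranges overlap. In a principal component analysis the leading component held 20.3% of the variance, with the 3 azoxystrobin libraries at 11.2 to 37.0 and the 3 VdAL libraries at 11.8 to 35.2. The water libraries lay at −53.3 to −2.01 and the combination libraries at −33.7 to −11.5 on that component. Water and the combination parted on the next component, which held 16.7%, except for water replicate 3 at −4.25, nearer the combination libraries than its own group. The spread between replicates was widest in water, with a common biological coefficient of variation of 23.6%, against 18.5% in azoxystrobin, 17.8% in VdAL and 14.6% in the combination.

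Leaves given azoxystrobin differed from leaves given water in 569 genes, of which 454 were lower and 115 were higher. The lower genes had a median log2 fold change of −1.18 and the higher genes one of 0.63. The gene with the smallest p, BGIOSGA033447, fell from 183 ± 26.2 CPM in water to 39.2 ± 8.55 CPM in azoxystrobin, a log2 fold change of −2.23 (SE 0.17, adjusted p = 8.8e-06). BGIOSGA001968 fell from 89.6 ± 11.6 to 23.7 ± 3.83 CPM, by 1.92 on the log2 scale (SE 0.18, adjusted p = 7.49e-05). Among the genes that rose, BGIOSGA031188 went from 37.5 ± 3.29 to 82.5 ± 7.46 CPM (log2 1.14, SE 0.15, adjusted p = 0.00121), and BGIOSGA014122 from 160 ± 12.2 to 288 ± 30.02 CPM (log2 0.85, SE 0.12, adjusted p = 0.00154). For these 4 IDs the 3 azoxystrobin libraries all lay on the same side of the 3 water libraries. A change of at least 2-fold was estimated for 306 of the called genes, 289 lower and 17 higher. The 95% interval of the change lay within 2-fold in either direction for 13685 genes, or 64.0% of those tested. The share of calls that were higher was 20.2%, and it was 40.8% when library sizes were used without scaling factors and 32.7% with DESeq2, which called 1034 genes. The count was 130 without azoxystrobin replicate 3, 309 without azoxystrobin replicate 2 and 252 without water replicate 1.

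VdAL alone gave 758 genes that differed from water, 608 lower and 150 higher. Their median log2 fold changes were −1.01 and 0.65. BGIOSGA033447 and BGIOSGA001968 had the smallest p among lower genes in this comparison too. BGIOSGA033447 stood at 41.3 ± 6.12 CPM in VdAL (log2 −2.15 against water, SE 0.17, adjusted p = 1.36e-05) and BGIOSGA001968 at 24.0 ± 5.87 CPM (log2 −1.90, SE 0.18, adjusted p = 7.71e-05). BGIOSGA014122 rose to 335 ± 16.4 CPM (log2 1.06, SE 0.12, adjusted p = 0.000271). BGIOSGA010848 rose from 138 ± 17.7 CPM in water to 277 ± 26.4 CPM in VdAL (log2 1.01, SE 0.12, adjusted p = 0.0006). At least 2-fold change was estimated for 331 of the called genes, and the 95% interval lay within 2-fold for 13835 genes (64.7%). Higher genes made up 19.8% of the calls, and 36.3% with library sizes alone, while DESeq2 called 1153 genes. Leaving out VdAL replicate 3 gave 146 genes, VdAL replicate 2 gave 489 and water replicate 1 gave 432.

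The combination differed from water in 366 genes, 261 lower and 105 higher. Median log2 fold changes were −1.10 and 0.75. BGIOSGA033447 was again the gene with the smallest p, at 55.7 ± 8.05 CPM in the combination (log2 −1.72 against water, SE 0.17, adjusted p = 0.00032). BGIOSGA007686 fell from 50.9 ± 4.39 to 16.4 ± 1.94 CPM (log2 −1.63, SE 0.18, adjusted p = 0.000622). BGIOSGA031188 rose to 92.8 ± 9.78 CPM (log2 1.31, SE 0.15, adjusted p = 0.000622), and BGIOSGA004313 rose from 784 ± 18.1 to 1448 ± 143 CPM (log2 0.89, SE 0.12, adjusted p = 0.00195). An estimated change of 2-fold or more was seen for 169 of the called genes, and the 95% interval lay within 2-fold for 13879 genes (64.9%). DESeq2 called 741 genes. The count was 711 without water replicate 3, 134 without water replicate 2, 198 without water replicate 1, 138 without combination replicate 1 and 110 without combination replicate 3.

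**Figure D1:**
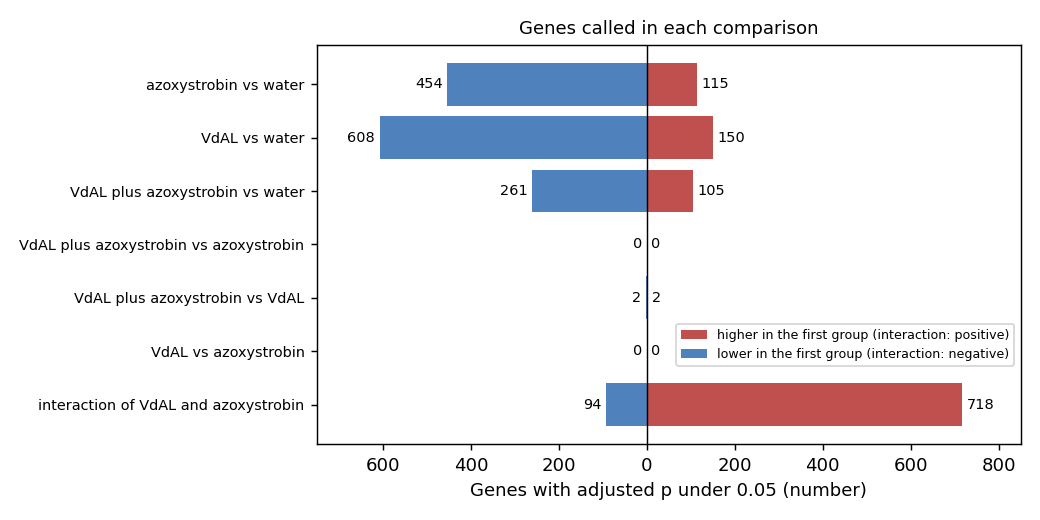
Number of genes with adjusted p under 0.05 in each of the 7 comparisons (edgeR quasi-likelihood test, 3 libraries per group), with genes lower in the first-named group to the left of 0 and genes higher in it to the right; for the interaction, negative values are to the left and positive to the right. Lower genes outnumber higher genes in the 3 comparisons with water (454 to 115, 608 to 150 and 261 to 105), and the interaction has 718 positive and 94 negative genes.

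**Figure D2:**
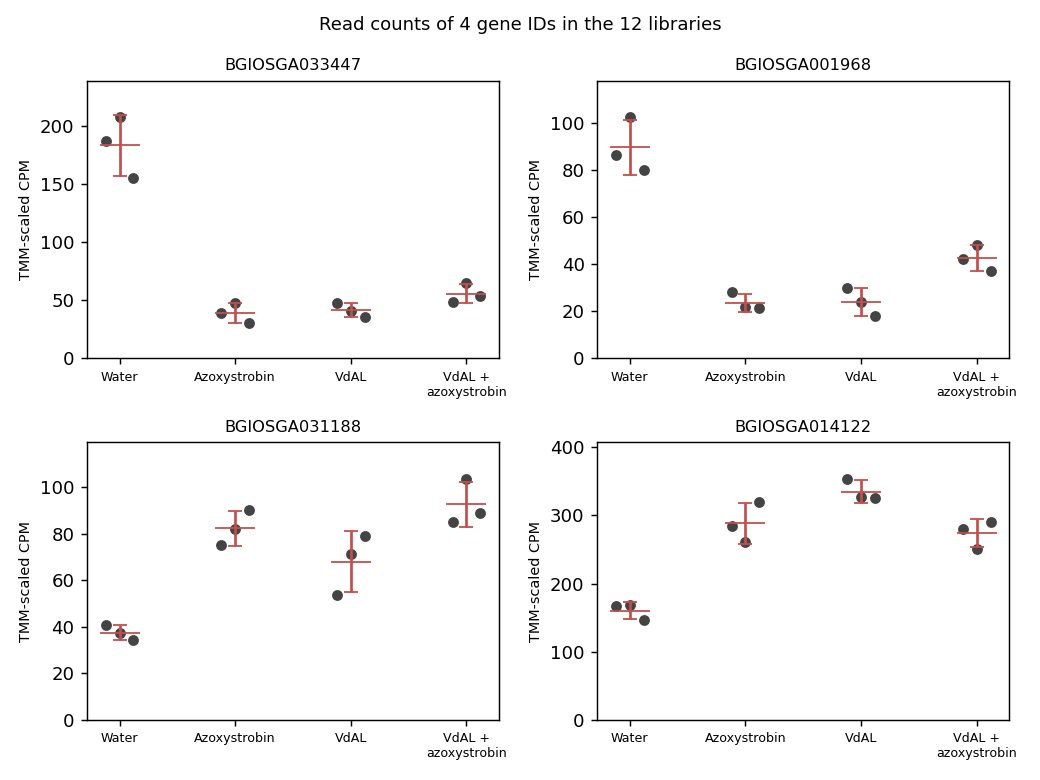
TMM-scaled CPM of 4 gene IDs in each of the 12 libraries, grouped by treatment on the horizontal axis; points are libraries, the long red line is the mean and the bar is ±1 SD of 3 libraries. The levels of BGIOSGA033447 and BGIOSGA001968 are lower in the 9 treated libraries than in the 3 water libraries, and those of BGIOSGA031188 and BGIOSGA014122 are higher.

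The genes called in the single treatments overlapped. Of the genes lower in azoxystrobin and those lower in VdAL, 327 were shared, where independent lists of the same length would share 12.9. Of the higher genes 58 were shared against 0.807 for independent lists, and 0 genes were called in opposite directions. Simulated unchanged groups set against a shared simulated control had at most 1 lower and 0 higher genes in common in 20 simulations. With no gene changed few can be called, so these counts do not measure how far shared controls raise the overlap of long lists. Across all tested genes, which are not independent replicates, the fold changes of azoxystrobin and VdAL correlated at r = 0.756 (Spearman 0.740), against 0.508 in the simulations. Their covariance was 0.176, against 0.0626 ± 0.0014 (SD of 20 simulations) from a simulated shared control. The simulations drew each gene independently, so that SD leaves out variation that genes share and is too small a yardstick. In random regroupings of the real libraries, which share a control in the same way, the highest covariance apart from the real grouping was 0.153. With 3 water libraries the controls could not be split into sets of 2 or more, so part of the excess in the overlaps may come from the shared controls.

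The combination shared 109 lower and 35 higher genes with azoxystrobin, where independent lists would share 5.54 and 0.565. With VdAL it shared 113 lower and 47 higher genes, where independent lists would share 7.42 and 0.737. The simulations gave 0 shared genes in each of these, again with no gene changed, so they do not measure the part due to shared controls. Across all tested genes the fold changes of the combination correlated at r = 0.555 with those of azoxystrobin and 0.544 with those of VdAL. The simulations gave 0.494 and 0.499, which is not far below. All 3 treated groups were called lower than water in 88 genes and higher in 26 genes. Those 88 genes had median log2 fold changes of −1.28 in azoxystrobin, −1.10 in VdAL and −1.10 in the combination. For the 26 genes the medians were 0.71, 0.79 and 0.77.

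The 327 genes lower in both single treatments had a smaller median decrease in the combination. Their median log2 fold change against water was −1.16 in azoxystrobin, −1.11 in VdAL and −0.62 in the combination. In 323 of them the combination estimate was below water, in 276 it was above both single treatments, and in 272 it was above both and still below water. The interaction passed the threshold in 273 of the 327, all positive, while the direct tests of the combination against azoxystrobin and against VdAL called 0 and 4 genes in all. These genes were chosen for low values in the single treatments relative to water, which by itself favours a smaller decrease in the combination and a positive interaction, so the counts are not independent evidence of either. The 58 genes higher in both single treatments had medians of 0.64, 0.68 and 0.63 in azoxystrobin, VdAL and the combination, and 33 of them had a negative interaction, which their selection favours in the same way.

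**Figure D3:**
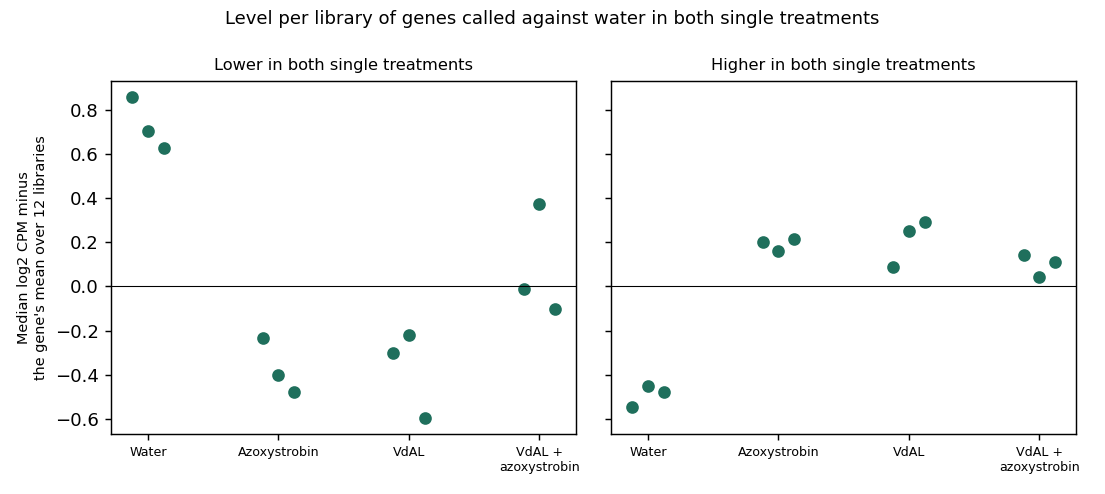
Median, over the 327 genes called lower than water in both single treatments (left) and the 58 called higher (right), of each gene's log2 CPM minus its mean over the 12 libraries; each point is a library. In the left panel the water libraries lie at 0.63 to 0.86, the azoxystrobin libraries at −0.48 to −0.23, the VdAL libraries at −0.60 to −0.22 and the combination libraries at −0.10 to 0.37.

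Adding VdAL to azoxystrobin gave 0 genes with an adjusted p under 0.05 in edgeR's quasi-likelihood test of the combination against azoxystrobin, and the smallest adjusted p was 0.0838. At an unadjusted p under 0.05 there were 2574 genes. The ID that fell in both single treatments, BGIOSGA033447, stood at 39.2 ± 8.55 CPM in azoxystrobin and 55.7 ± 8.05 CPM in the combination, a log2 difference of 0.51 (95% interval 0.14 to 0.87, adjusted p = 0.271). BGIOSGA001968 stood at 23.7 ± 3.83 and 42.5 ± 5.42 CPM, a log2 difference of 0.84 (95% interval 0.46 to 1.23, adjusted p = 0.0999). Under 17 alternatives that difference ran from 0.74 to 0.99. It was called under 3 of them, which were DESeq2, the edgeR test on these 6 libraries alone and the fit without a filter. BGIOSGA033447 was called under 1, the fit without a filter. The 95% interval lay within 2-fold for 14046 genes (65.7%). DESeq2 called 192 genes, 132 of them higher and 60 lower, voom with a spread per group called 33 (28 higher, 5 lower), and the edgeR test on these 6 libraries alone called 145 (131 higher, 14 lower). The count was 7 without azoxystrobin replicate 1 and 4 without azoxystrobin replicate 2, all higher in the combination, but 13 without azoxystrobin replicate 3 and 1 without combination replicate 2, all lower.

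Adding azoxystrobin to VdAL gave 4 genes, 2 higher and 2 lower in the combination than in VdAL. BGIOSGA007859 stood at 30.05 ± 4.78 CPM in VdAL and 129 ± 36.4 CPM in the combination (4.29-fold, log2 SE 0.31, adjusted p = 0.0404). BGIOSGA030767 rose from 4.25 ± 0.938 to 17.4 ± 5.60 CPM (log2 2.02, SE 0.31, adjusted p = 0.0404). BGIOSGA039400 fell from 42.7 ± 5.82 to 20.1 ± 2.24 CPM (log2 −1.09, SE 0.17, adjusted p = 0.0404), and BGIOSGA033925 from 14.1 ± 2.77 to 2.97 ± 0.237 CPM (log2 −2.24, SE 0.36, adjusted p = 0.049). In water BGIOSGA007859 stood at 135 ± 65.4 CPM and BGIOSGA030767 at 12.4 ± 5.07 CPM. An unadjusted p under 0.05 was found for 2735 genes, and the 95% interval lay within 2-fold for 14022 genes (65.6%). DESeq2 called 312 genes, 217 higher and 95 lower, the edgeR test on these 6 libraries alone called 386, voom called 151, and library sizes alone gave 4 higher and 19 lower, while with the share of reads not aligned uniquely as a covariate 1 of the 4 IDs, BGIOSGA039400, stayed called. The count was 58 without VdAL replicate 1, 7 without combination replicate 1, and 0 when VdAL replicate 2 or 3 or combination replicate 2 or 3 was left out.

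The single treatments were not told apart. The edgeR test of VdAL against azoxystrobin called 0 genes, the smallest adjusted p was 0.298, and 718 genes had an unadjusted p under 0.05. DESeq2 called 7 genes and voom 0. BGIOSGA033447 differed by 0.08 on the log2 scale between the single treatments (95% interval −0.28 to 0.44) and BGIOSGA001968 by 0.02 (95% interval −0.37 to 0.40). Both differences fell below 0 without azoxystrobin replicate 3, without VdAL replicate 1 and with the share of reads not aligned uniquely as a covariate, and that of BGIOSGA001968 also without azoxystrobin replicate 2 and with voom. The largest differences among the IDs named here were those of BGIOSGA007859, at 64.2 ± 20.3 CPM in azoxystrobin and 30.05 ± 4.78 CPM in VdAL (log2 −1.10, 95% interval −1.73 to −0.46, adjusted p near 1), and BGIOSGA033925, at 8.48 ± 2.62 and 14.1 ± 2.77 CPM (log2 0.74, 95% interval 0.07 to 1.42). BGIOSGA007859 was called under 1 of 17 alternatives, the fit without a filter, and its difference was −0.68 with the covariate. The median absolute log2 difference over all tested genes was 0.15 and the median width of the 95% interval to either side was 0.49. The interval lay within 2-fold for 15168 genes (70.9%), so for the other genes a difference of 2-fold or more was not excluded. The count of 0 does not show that the treatments act alike.

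The interaction asks whether the effect of VdAL differed between leaves with and without azoxystrobin, or equally whether the effect of azoxystrobin differed with and without VdAL. It passed the threshold in 812 genes, 718 positive and 94 negative. A positive value means that the combination lay above the sum of the single log2 effects. BGIOSGA033447 fell by more than 2 log2 units in each single treatment and by 1.72 in the combination, which gave an interaction of 2.66 (SE 0.24, adjusted p = 5.9e-05). For BGIOSGA001968 the interaction was 2.75 (SE 0.26, adjusted p = 5.9e-05), with 42.5 ± 5.42 CPM in the combination against 89.6 ± 11.6 CPM in water. Among negative values, BGIOSGA014122 stood at 274 ± 20.5 CPM in the combination, 335 ± 16.4 CPM in VdAL and 288 ± 30.02 CPM in azoxystrobin (interaction −1.14, SE 0.16, adjusted p = 0.00137). BGIOSGA010848 had an interaction of −1.09 (SE 0.18, adjusted p = 0.00237). Its levels were 209 ± 16.3 CPM in the combination, 222 ± 13.3 CPM in azoxystrobin and 277 ± 26.4 CPM in VdAL. For neither ID was the combination called different from a single treatment. Against water the combination was higher by 0.77 for BGIOSGA014122 and 0.60 for BGIOSGA010848 on the log2 scale. In the 718 positive genes, which were chosen by a contrast built from these same values, the median log2 fold change against water was −0.85 in azoxystrobin, −0.91 in VdAL and −0.24 in the combination.

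The positive share of the interaction calls was 88.4%. It was 75.7% of 1348 calls with DESeq2, and with library sizes alone it was 50.8% of 970 calls, 493 positive and 477 negative. That scaling moved the median interaction of all tested genes from −0.0013 to −0.19 and the median difference between combination and azoxystrobin to −0.10. With TMM factors, the fold changes are relative to a median gene near 0. These factors were 0.952 to 0.982 in water and 0.926 to 0.987 in the combination. In azoxystrobin they were 1.03 to 1.04 and in VdAL 0.994 to 1.05. They thus divide the libraries in the same way as the interaction does. With the share of reads not aligned uniquely as a covariate the interaction called 539 genes, 469 positive and 70 negative, and 399 of the 812 stayed called. In the 413 that did not, the median absolute log2 value went from 1.26 to 1.14 and the median SE from 0.30 to 0.35. The count was 1253 without water replicate 2, 1242 without VdAL replicate 1, 442 without azoxystrobin replicate 3, 311 without VdAL replicate 3 and 291 without combination replicate 2.

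The effect of each agent was also compared between backgrounds without any library in common. Across the 21381 genes, the VdAL effect without azoxystrobin correlated with that on top of azoxystrobin at r = −0.263 (Spearman −0.252, SE 0.149 by leaving out each library). For the azoxystrobin effect without and with VdAL r was −0.216 (Spearman −0.203, SE 0.196). Simulated unchanged groups, with each gene drawn independently, gave −0.00405 and −0.00545. In random regroupings of the real libraries the correlation for VdAL ran from −0.313 to 0.290. Regroupings at −0.313 and −0.285 were more negative than the real grouping, so the real value was not outside that range. Regroupings mix treatment differences into the groups, so they are not a pure case of no effect. Over the 745 genes that differed among the 4 groups, r was −0.407 for VdAL and −0.319 for azoxystrobin. Without water replicate 3 the values over all genes were −0.127 and −0.0513. Both correlations were thus under 2 SE from 0, and an opposite effect of either agent on the other background was not established.

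**Figure D4:**
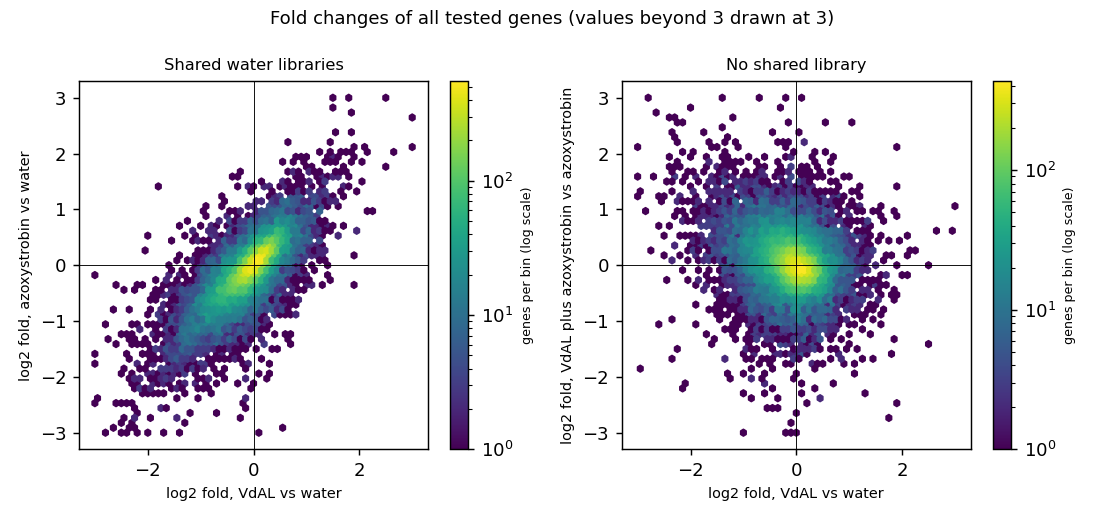
Log2 fold changes of all 21381 tested genes, with colour for the number of genes per bin on a log scale and values beyond 3 drawn at 3. On the left, azoxystrobin against VdAL, both relative to the same water libraries (r = 0.756); on the right, the effect of VdAL on top of azoxystrobin against its effect alone, with no library in common (r = −0.263).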

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

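The tests of library scaling and of an unlabelled batch, and the fits with library sizes alone, with a spread per group and with the share of reads not aligned uniquely, were chosen after results had been seen; the other tests were set beforehand.

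The effects of VdAL without and with azoxystrobin differed, by a test of the interaction, in 812 genes. Among the IDs named in the report, the interaction log2 value was 2.66 for BGIOSGA033447, 2.75 for BGIOSGA001968, 3.17 for BGIOSGA007859 and 2.95 for BGIOSGA030767. Negative values were found for BGIOSGA014122 at −1.14, BGIOSGA010848 at −1.09 and BGIOSGA039400 at −1.11. Each of these 7 IDs had an interaction with an adjusted p under 0.05 in edgeR's quasi-likelihood test. They were picked by smallest p in the interaction or in comparisons that share libraries with it, which favours large values. The other named IDs, BGIOSGA031188, BGIOSGA004313, BGIOSGA007686 and BGIOSGA033925, did not pass. Behind the value of BGIOSGA007859 the water libraries ran from 75.7 to 205 CPM.

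In reads that enter no comparison, VdAL replicate 1 had 22.4% of its reads not aligned uniquely (95% Wilson interval 22.34 to 22.37, counting error only), where the water libraries spanned 9.01% to 16.1%. Reads that fit more than 1 gene made up 0.833% in VdAL replicate 2, where the water libraries spanned 0.646% to 0.830%, and its 95% Wilson interval of 0.829 to 0.838 overlaps that of water replicate 1, 0.826 to 0.834, so it was not distinguished from water.

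Of the 718 genes chosen by a positive interaction, which itself favours this order of estimates, 536 had a combination estimate above both single treatments and below water. Of 100 regroupings of the 12 libraries 1, the real one, reached 812 calls, and the highest of the others gave 162. That argues against libraries that differ by no treatment at all. It is not a test of the interaction alone, because regroupings mix treatment differences into the spread. If the 3 libraries of a treatment are technical, it also leaves chance between plants or plots open. An offset of the water libraries as the sole source of the calls is argued against. That holds unless the 3 libraries of a treatment are technical or each treatment had its own area. With water kept fixed and the other 6 treated libraries pooled, 1 of 84 ways to pick the combination from the 9 treated libraries reached the real 855 calls, with 430 as the highest other. The same pooled fit with water left out of the contrast called 141 genes. Whether a water offset supplied part of the 855 calls is not decided by these splits. Voom with a spread per group gave 837 calls, 103% of the main number, 752 of them shared. That fit changed the test as well as the spread, so it does not decide whether a larger spread among the water libraries contributed. With the share of reads not aligned uniquely as a covariate 399 of the 812 calls stayed among 539, and in the 413 lost the median absolute log2 value went from 1.26 to 1.14 and the median SE from 0.30 to 0.35, while the median of the 718 positive genes stayed at 99.2% of its value, so that share is argued against as the whole source of the size but not as a source of part of the calls. An unlabelled batch that put the water and combination libraries on a side apart from the single treatments cannot be told apart from the 812 interaction calls, because no day, plot or run is labelled, so a response to the combination that is smaller than the sum of the single responses may be put forward only as a hypothesis.

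The excess of positive over negative interaction calls, 718 against 94 or a positive share of 88.4%, is a separate matter from their size. The share was 85.7% with RLE factors, 83.6% with upper-quartile factors and 50.8% with library sizes alone. Dropping the factors moves the median interaction of all genes to −0.19, which lowers the positive share whatever its cause, so scaling of the libraries as a source of the excess was neither supported nor excluded by this test. For the size of the positive values the same step left the median at 87.2% of its value (1.29 in place of 1.48) and 493 of the 718 genes still called. Most of the size was thus present without TMM factors. Because the step moves all genes by about the same amount, genes chosen for large values keep most of their size whatever the cause. It therefore does not decide whether another error of scaling contributed. In the 225 lost the median went from 1.06 to 0.87 and the median SE from 0.27 to 0.26, so their calls ended with the shift.

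That azoxystrobin and VdAL moved many of the same genes relative to water could come from the water libraries they share. The covariance of their fold changes, 0.176, was reached in 1 of 100 regroupings of the 12 libraries, the real one, with 0.153 as the highest other, which argues against the shared libraries as the whole cause. A common offset of the 3 water libraries, from area, day or handling, was not tested apart from treatment and stays open.

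Splits of the 6 libraries of each comparison of groups were too few for a share under 0.05, at 10 each. For azoxystrobin against water 1 split, the real one, gave 569 calls, and the highest other gave 146. For VdAL against water 1 split gave 758 and the highest other 24, for the combination against water 1 split gave 366 and the highest other 0, and for the combination against VdAL 1 split gave 4 and the highest other 0. For the combination against azoxystrobin all 10 splits gave at least the real count of 0, with 1 as the highest other, and for VdAL against azoxystrobin all 10 gave 0.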

How the results depend on the processing

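The fits with library sizes alone, voom and the covariate were chosen after seeing the data; the other alternatives were set beforehand. Fold changes of IDs in the comparisons they were picked for by smallest p, and both correlations between backgrounds, kept their sign. The differences of BGIOSGA033447 and BGIOSGA001968 between VdAL and azoxystrobin changed sign under 3 and 5 of 17 alternatives. The calls of the IDs named for the comparisons with water and for the interaction held under each alternative run, and the 4 IDs of the combination against VdAL kept their direction but missed the threshold under 6 or 7 of 17. Counts stayed within 1.5 times with RLE factors, upper-quartile factors, the filter of 1 CPM in 3 libraries (22384 genes kept) and removal of the 20 most abundant genes, in all 7 comparisons.

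Counts are given in the order azoxystrobin, VdAL and combination against water, combination against azoxystrobin, combination against VdAL, VdAL against azoxystrobin, and interaction. The main counts were 569, 758, 366, 0, 4, 0 and 812. DESeq2 gave 1034, 1153, 741, 192, 312, 7 and 1348, and the cause was not tested. Without a filter the counts were 1385, 1438, 1048, 818, 944, 54 and 1752; this fit took 36532 genes, and its estimate of how far gene spreads differ became infinite prior degrees of freedom in place of 8.9, so each gene was given the trend's spread. The compared groups alone gave 340, 440, 177, 145, 386 and 0. Fewer libraries stood behind the spread, and the counts against water fell. Those of the combination against each single treatment rose. The water libraries, left out of these last fits, had the widest spread (common biological coefficient of variation 23.6%, against 14.6% to 18.5%). Whether the spread of water held down the main counts of 0 and 4 was not tested. Voom moved the combination against azoxystrobin to 33 and against VdAL to 151, and library sizes alone moved the latter to 23 (4 higher, 19 lower); these causes were not tested. The covariate moved the interaction to 539, 399 of them shared with the main calls, and the 413 lost had a lower median size and a larger median SE than before.

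Leaving out each library in turn gave 130 (without azoxystrobin replicate 3) to 563 for azoxystrobin, 146 (without VdAL replicate 3) to 874 for VdAL, and 110 (without combination replicate 3) to 711 (without water replicate 3) for the combination. It gave 0 to 13 for the combination against azoxystrobin (7 and 4 all higher, 13 and 1 all lower), 0 to 58 (without VdAL replicate 1) against VdAL, 0 to 0 for VdAL against azoxystrobin, and 291 (without combination replicate 2) to 1253 (without water replicate 2) for the interaction. Fewer libraries lower the power; why some omissions raised counts was not tested.

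The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at −0.205 to 0.104 (mean −0.0147), and 3 of 12 libraries correlated best with their own number. With the replicate block the counts were 494, 655, 324, 0, 0, 0 and 621; the combination against VdAL went from 4 to 0, each of the 4 IDs having an adjusted p of 0.0698. The alternatives planned for gene lists were not run, since 0 of the IDs matched the japonica table used here. Small effects can be missed at the size of this study: in simulations 53 of 100 genes changed 2-fold were called for azoxystrobin against water. Depth and replicate number were not varied.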

Other observations

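The comparison of the combination with the mean of the single treatments was set before its count was seen, as was the comparison of the ID series.

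Of the 261 genes called lower in the combination than in water, 179 had a combination estimate below both single treatments, while the interaction past the threshold was positive in 51 of the 261 and negative in 4. Their median log2 fold changes were −0.69 in azoxystrobin, −0.69 in VdAL and −1.10 in the combination. BGIOSGA007686 was of this kind, at 26.9 ± 6.71 CPM in azoxystrobin, 28.9 ± 2.98 CPM in VdAL and 16.4 ± 1.94 CPM in the combination against 50.9 ± 4.39 CPM in water (mean ± SD, n = 3), with an interaction of 0.11 (95% interval −0.43 to 0.65). Of the 105 genes called higher in the combination, 70 had an estimate above both single treatments, with medians of 0.47, 0.54 and 0.75. These genes were chosen by their level in the combination, so the estimates there are expected to be the most extreme even without a difference between treatments.

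Pooling azoxystrobin and VdAL libraries into a group of 6 and leaving water out of the contrast, 141 genes differed between the combination and the single treatments, 116 of them higher in the combination. Of 84 ways to pick 3 of the 9 treated libraries 1, the real one, reached that count, and the highest other gave 6. The 9 libraries were thus not interchangeable. Technical replicates or an area for each treatment would give the same result, so chance between plants or plots is not excluded. The same 6 libraries against water gave 1334 calls. Under the other ways to pick, the remaining 6 libraries against water gave 278 to 1136. A pooled group of 6 is not comparable with the counts for groups of 3.

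IDs starting with EPlOING were called in a test over all 4 groups less often than IDs starting with BGIOSGA, in 12 of 1300 (0.923%) against 733 of 20081 (3.65%). Their median level was lower, at a log2 CPM of 1.69 against 4.06. Draws of BGIOSGA IDs matched on level had 12 to 28 called (central 95% of 10000 draws, median 20), a range whose lower end is the observed 12.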
